A study of Caenorhabditis elegans with 12 samples.

How the data were processed

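Whole C. elegans were collected on day 1 of adulthood at 20 °C, 3 libraries for each of N2, nfyb-1(cu13), isp-1(qm150) and the double mutant, and poly(A) RNA was made into libraries with a directional kit, per the labels' protocols. The table has the column layout of Cuffdiff. HISAT 0.1.6, StringTie 1.0.4, Cuffdiff 2.2.1 and the genome build WBcel235 are named in the submitters' processing notes, with no role or order. How reads shared by gene copies were divided, and whether counting used strand, is not given in the sources used here.

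The data analysed are a table of the authors' comparisons, with 277062 rows that hold 46177 gene identifiers in each of 6 comparisons of genotypes. Per the file headers, the authors deposited for each row an FPKM value of each of the 2 genotypes (fragments scaled to transcript length and library size, with the 3 libraries merged), a log2 fold change, a test statistic (a score with no fixed range), a p-value and a q-value. The deposited log2 fold was the ratio of the second to the first FPKM value, within 4.29e-05. The smallest p-value the authors deposited was 5e-05, shared by 93 to 1239 features in the planned comparisons, so the strongest calls cannot be ranked by p or q. FPKM values do not show how many fragments lie behind a value, so the depth is unknown and no counting interval is given. An exact 0 is described as listed at 0, with no fold.

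Several identifiers often repeat a tested unit, since overlapping genes were tested together. Rows with the same gene string were therefore reduced to 1 feature, which left 41926 features, 3032 of them merged from several genes. Benjamini-Hochberg adjustment of the deposited p-values over the 72966 tests of these features in all 6 comparisons gave the deposited q-values within 5.26e-07. Of 46177 identifiers, 43161 had a current symbol in the reference table, and symbols in that table stand in for sequence names. Positions are from the Ensembl release 115 annotation of WBcel235, the build the submitters name. Of 11422 tested features of a single gene with an identifier in that annotation, 11421 had a locus that overlaps the annotated gene.

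The design fixed before the data were examined foresaw per-library values and, failing these, the authors' own tests. The second case held: a feature was called at q under 0.05 in the authors' deposited table, with no test across libraries added, for 5 comparisons. Gene lists were fixed before the data were examined. A feature joined a list by its name in the table or its current symbol, and a merged feature only if all its genes were members. For each list with at least 3 tested members, the called share was set against that of all other tested features by Fisher's exact test, 2-sided, adjusted by Benjamini-Hochberg over the 41 lists within a comparison. A test of the rises alone and of the falls alone, added after the data were seen, is given in the report for described lists, and in the closing section for other lists, where it passed and the 2-sided test did not, or did not under an alternative (the proteasome in nfyb-1;isp-1 versus N2). Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of the list's members. Gene Ontology terms from the authors' table with 10 to 500 tested features were, as a test added after the data were seen, compared by Fisher's exact test, for rises and falls apart, among tested features with a term. Agreement between backgrounds used correlations across features and the overlap of calls beside n1 × n2 / N.

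Named genes follow a rule fixed before the data were examined: 14 genes in every comparison, the 6 largest rises and 6 largest falls of called protein genes with a symbol and at least 5 FPKM in the higher genotype, and up to 4 members of a described list by q and then fold. Other named genes are said to have been chosen after their values were seen.

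The interaction test, added after the data were seen, divided each log2 fold by the deposited statistic times 1.74 (nfyb-1 versus N2) or 1.75 (nfyb-1;isp-1 versus isp-1), the median factor between the statistic and the normal deviate of its p-value, to obtain a standard error. It was tested on simulated data for that comparison with 11268 features: 47 of 100 features with a log2 difference of 1, 74 of 100 with a difference of 2 and 4 of 11068 with no difference were called. The simulated noise was drawn from these same standard errors, so the simulation cannot check the factors 1.74 and 1.75. The list test was tested on simulated calls for nfyb-1 versus N2 with 11669 features: 82 of 100 lists with 4 times the called share and 2 of 672 lists with no planted change passed. These calls were drawn independently for each feature. Fisher's exact test also takes genes as independent, so neither allows for genes of a list that move together. Alternatives were a threshold of 0.01, an absolute log2 fold of at least 1, a mean of at least 5 FPKM, pseudocounts of 1 and 0.1, quantile normalization of the 4 genotype columns and, added later, other adjustment families and counting units. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.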

Results

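Poly(A) RNA from whole Caenorhabditis elegans was sequenced on day 1 of adulthood, from animals grown at 20 °C with unrestricted bacterial food. The 12 libraries fell into 4 genotypes with 3 libraries each. N2 is the wild-type laboratory strain, and nfyb-1(cu13) carries a mutation in nfyb-1, the B subunit of the CCAAT-binding transcription factor NF-Y. The isp-1(qm150) strain carries a mutation in the Rieske iron-sulfur protein of respiratory complex III, a long-lived mitochondrial mutant, and the last strain carries both mutations. The title of the series links NFYB-1 to mitochondrial function, longevity and lysosomal prosaposin. The nfyb-1 effect was read in the N2 and in the isp-1 background, and the isp-1 effect with and without nfyb-1.

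The values used here are the authors' FPKM for each genotype, with the 3 libraries merged, and the authors' tests between genotypes. The error between libraries and the depth of each library are not in those columns, so no SD accompanies a value. The q in the authors' deposited table is the statement about replicate error. Summed over all features, the authors' deposited table held 968878 FPKM for N2, 958765 for nfyb-1, 896488 for isp-1 and 970747 for nfyb-1;isp-1. The labels do not say whether the 3 libraries came from separate cultures, so each q measures only the spread between these libraries, which can be technical. A feature below is a tested unit of the table, which is a gene or, for 3032 of 41926 features, overlapping genes tested as a merged unit. Folds are given on the log2 scale.

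The targeted gene was examined first. The nfyb-1 gene (WBGene00021132; WBcel235, chromosome II, 461667 to 467365, minus strand, protein-coding) stood at 31.5 FPKM in N2, 4.27 in nfyb-1, 31 in isp-1 and 2.93 in nfyb-1;isp-1 in the authors' deposited table. It fell by 2.89 on the log2 scale against N2 and fell by 3.40 against isp-1, each at q = 0.000982, the smallest q in the authors' deposited table. The other NF-Y subunits were not called: nfya-1 stood at 13.4 and 13.7 FPKM, nfya-2 at 31.1 and 29.7, and nfyc-1 at 66.5 and 58.1 in N2 and nfyb-1 in the authors' deposited table. The isp-1 gene (WBGene00002162; WBcel235, chromosome IV, 8134016 to 8136055, minus strand, protein-coding) ranged from 296 FPKM in N2 to 361 in nfyb-1;isp-1 in the authors' deposited table, with no call. In the 5 comparisons none of these 4 genes was called, nor was nfyb-1 in isp-1 versus N2 (log2 fold -0.027, q = 0.934) or in nfyb-1;isp-1 versus nfyb-1 (-0.54, q = 0.213) in the authors' deposited table. The isp-1 allele changes a codon, so this level does not check the isp-1 labels.

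**Figure D1:**
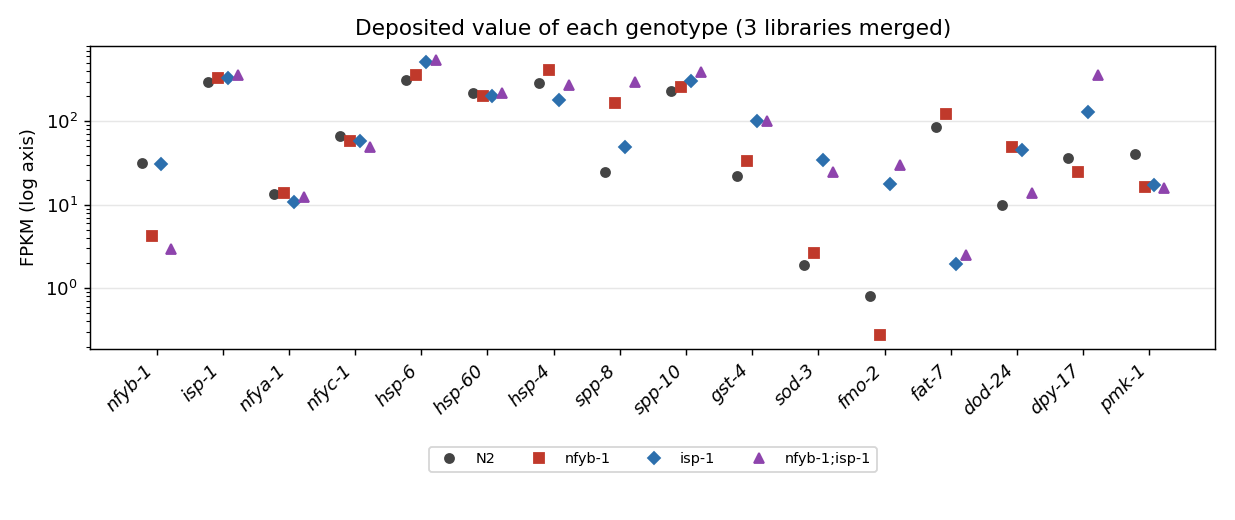
FPKM of 16 genes in each genotype on a log axis, from the authors' deposited table; each point is 1 genotype with its 3 libraries merged, and no error bar can be drawn. nfyb-1 stands near 31 FPKM in N2 and isp-1 and below 5 in both strains with the nfyb-1 mutation, and spp-8 rises from 24.4 FPKM in N2 to 165 in nfyb-1 and 295 in nfyb-1;isp-1.

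In nfyb-1 animals against N2, the saposin-like gene spp-8 showed the largest rise among called protein genes with a symbol and at least 5 FPKM in the higher genotype. It went from 24.4 to 165 FPKM (log2 fold 2.75, q = 0.000982) in the authors' deposited table, and lies on chromosome IV from 8481664 to 8483621 (WBGene00004993, WBcel235). Besides spp-8, 8 of 9 mRNA features of the mitochondrial genome, 16 of 29 muscle genes, 11 of 41 lysosomal features and 29 cuticle collagen genes rose. In all, 689 features rose and 314 fell among 11669 tested at q under 0.05 in the authors' deposited table. Of these calls, 6 rises and 42 falls were listed at 0 in a genotype and have no fold. The median absolute log2 fold of the other calls was 0.56.

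After spp-8, the largest rises in the authors' deposited table were the F-box gene fbxa-192 (log2 fold 2.46), the RNA-binding protein gene tiar-2 (2.35), dod-24 (2.28), the ABC transporter gene haf-6 (2.17), each at q = 0.000982, and the claudin-like gene clc-24 (1.96, q = 0.00880). Besides nfyb-1, the largest falls there were pud-1.2 (log2 fold -3.34), the p38 kinase genes pmk-3 (-2.27) and pmk-2 (-1.80), pud-3 (-1.80) and the dystrobrevin gene dyb-1 (-2.22, q = 0.0174). Of these genes, fbxa-192, tiar-2, haf-6, clc-24, pud-1.2, pmk-3, pmk-2 and pud-3 were also called in the same direction in isp-1 and in nfyb-1;isp-1 against N2, with no call between the mutants. For tiar-2 the levels were 3.65 FPKM in N2, 18.6 in nfyb-1, 20.6 in isp-1 and 19.5 in nfyb-1;isp-1 in the authors' deposited table. In the authors' deposited table the ER chaperone gene hsp-4 rose by 0.51 (q = 0.000982), hlh-30, the TFEB homologue, by 0.49 (q = 0.000982) and the glutathione transferase gene gst-4 by 0.59 (q = 0.0185). The mitochondrial chaperone genes hsp-6 (log2 fold 0.17, q = 0.244) and hsp-60 (-0.15, q = 0.295) were not called in the authors' deposited table. Also not called were spp-10 (0.16, q = 0.332), sod-3 (0.46, q = 0.561) and the yolk gene vit-2 (0.18, q = 0.568) in the authors' deposited table.

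Of the lists fixed before the data were examined, 41 were tested, and in 11 the called share differed from that of the other features (Fisher's exact test, 2-sided, adjusted over the lists). Among 9 features of the mitochondrial genome, 8 rose and 1 did not pass, over all features and adjusted over the list alone (median log2 fold 0.56; Fisher's exact test, adjusted p = 2.48e-07). In the authors' deposited table ctb-1, cytochrome b, went from 1712 to 3161 FPKM (log2 fold 0.88), atp-6 merged with nduo-1 rose by 0.64 and ctc-2 and ctc-3 by 0.56, all at q = 0.000982. The nuclear-encoded subunits moved little: 0 of 13 features of complex I, 1 of 11 of complexes II and III, and 1 rise and 1 fall of 22 of complexes IV and V were called. Of 41 lysosomal features, 11 rose, 4 fell and 26 did not pass (12 rose and 5 fell adjusted over the list alone; adjusted p = 5.71e-06 by Fisher's exact test). They included the lipase gene lipl-5 (log2 fold 0.85), the cathepsin genes cpr-1 (0.76) and asp-3 (0.60), and the mannosidase gene aman-1 (-0.64), all at q = 0.000982 in the authors' deposited table. Of 18 saposin-like genes, 4 rose, 0 fell and 14 did not pass, also adjusted over the list alone, a share not past the threshold (adjusted p = 0.161 by Fisher's exact test). Besides spp-8 these were spp-18 (1.59, q = 0.000982), spp-23 (0.66, q = 0.0185) and spp-3 (0.33, q = 0.0321) in the authors' deposited table.

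Muscle genes gave the highest called share of the tissue lists: 16 of 29 rose, 0 fell and 13 did not pass (22 rose adjusted over the list alone; adjusted p = 3.76e-09 by Fisher's exact test). In the authors' deposited table the myosin genes myo-1 (log2 fold 0.91), myo-3 (0.57) and myo-2 (0.47) and the troponin gene tnt-4 (0.79) rose at q = 0.000982. Of the cuticle collagen genes, 29 rose, 3 fell and 91 did not pass (35 and 3 adjusted over the list alone; adjusted p = 1.08e-07 by Fisher's exact test). Here col-81 (1.13), col-129 (1.12) and col-139 (1.12) rose and col-95 fell by 1.12 in the authors' deposited table, each at q = 0.000982. Of 18 intestinal genes, 6 rose and 12 did not pass (8 rose adjusted over the list alone; adjusted p = 0.0123 by Fisher's exact test), among them the intermediate filament genes ifc-2 (0.62) and ifb-2 (0.47) in the authors' deposited table. Of 39 oocyte and germline genes, 3 fell, 0 rose and 36 did not pass (1 fall adjusted over the list alone), and their median log2 fold was -0.17. No sperm gene of 72 and no mitochondrial ribosome gene of 68 was called, fewer than among the other features (adjusted p = 0.0115 and 0.0143 by Fisher's exact test).

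Genes of the endoplasmic reticulum (ER) unfolded protein response changed both ways: 6 rose, 3 fell and 14 did not pass of 23 (8 and 3 adjusted over the list alone; adjusted p = 0.000455 by Fisher's exact test). In the authors' deposited table dnj-7 rose by 0.78 and the transcription factor gene xbp-1 by 0.61, whereas the disulfide isomerase gene pdi-2 fell from 454 to 176 FPKM (log2 fold -1.37) and the calreticulin gene crt-1 from 837 to 423 (-0.99), all at q = 0.000982. Among 82 C-type lectin genes, 18 rose and 11 fell (22 and 14 adjusted over the list alone; adjusted p = 5.05e-10 by Fisher's exact test). Among 49 antimicrobial effectors 10 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.00414 by Fisher's exact test). Of the lectins, clec-134, clec-197, clec-217 and clec-92 were listed at 0 in nfyb-1 and stood between 1.75 and 9.81 FPKM in N2 in the authors' deposited table. Called falls to 0 were not particular to nfyb-1. Over all features they numbered 42, 52 and 47 in nfyb-1, isp-1 and nfyb-1;isp-1 versus N2. In nfyb-1;isp-1 they numbered 5 against isp-1 and 1 against nfyb-1. The cytochrome P450 list held 4 rises and 6 falls among 39 (6 and 7 adjusted over the list alone; adjusted p = 0.00681 by Fisher's exact test). This list did not pass with calls at 0.01, with a log2 fold of at least 1 or with a mean of at least 5 FPKM. Of 24 genes of fatty acid synthesis, 5 rose (7 adjusted over the list alone; adjusted p = 0.137, and 0.0439 for rises alone, by Fisher's exact test), including the desaturase genes fat-5 (log2 fold 1.11), fat-6 (0.76) and fat-7 (0.54) in the authors' deposited table. Members of lectin, collagen and histone families share sequence, and how fragments were divided between copies is not given in the sources used here.

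**Figure D2:**
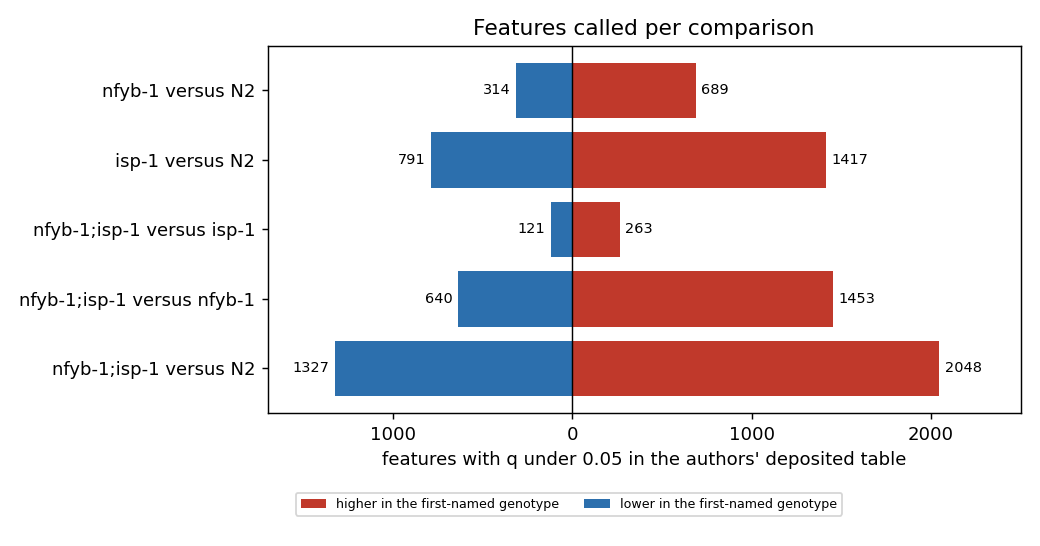
Number of features called at q under 0.05 in the authors' deposited table in each comparison, with those higher in the first-named genotype to the right of 0 and those lower to the left. The nfyb-1 mutation gave 689 rises and 314 falls against N2 and 263 and 121 against isp-1. The counts depend on the error between libraries as well as on the size of the effect.

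In isp-1 animals against N2, which asks what the respiratory chain mutation changes in the wild-type background, 58 of 125 cuticle collagen genes and 12 of 23 insulin signalling targets rose, and 19 of 32 proteasome and 26 of 70 cytosolic ribosome genes fell. There were 1417 rises and 791 falls among 12186 tested features at q under 0.05 in the authors' deposited table, with 49 rises and 52 falls listed at 0 in a genotype. The superoxide dismutase gene sod-3 went from 1.91 to 34.7 FPKM (log2 fold 4.19) and gst-4 from 22.4 to 102 (2.18) in the authors' deposited table, both at q = 0.000982. The largest rises there were the heme-responsive gene hrg-2 (5.43, or 4.36 with a pseudocount of 1, q = 0.00252), the methyltransferase gene comt-4 (4.65, q = 0.00929), the ammonium transporter gene amt-1 (4.56), cyp-13B1 (4.46), the flavin monooxygenase gene fmo-2 (4.46) and sod-3, the last 4 at q = 0.000982. The largest falls in the authors' deposited table were the stearoyl-CoA desaturase gene fat-7, from 84.9 to 1.93 FPKM (log2 fold -5.46), pud-1.2 (-4.05), the histone gene his-67 (-3.23, q = 0.0210), the aspartyl protease gene asp-12 (-3.17), cyp-35A3 (-2.94) and the yolk gene vit-3 (-2.68), the others at q = 0.000982.

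Among the fixed genes, hsp-6 rose from 317 to 520 FPKM (log2 fold 0.71), hlh-30 by 0.89 and spp-8 by 1.00 in the authors' deposited table, hsp-4 fell by 0.66, each at q = 0.000982. In the authors' deposited table hsp-60 (-0.15, q = 0.433), spp-10 (0.37, q = 0.0535) and vit-2 (0.46, q = 0.223) were not called. Of 17 genes of the mitochondrial unfolded protein response, 5 rose and 12 did not pass, also adjusted over the list alone (adjusted p = 0.382 by Fisher's exact test). With hsp-6 they included cyp-14A1 (1.60, q = 0.000982), the transcription factor gene atfs-1 (0.57, q = 0.00179) and timm-23 (0.44, q = 0.0193) in the authors' deposited table. Of 9 mitochondrially encoded features, only nduo-2 was called, a fall of 0.59 at q = 0.000982 in the authors' deposited table, and 2 rises and 1 fall passed adjusted over the list alone. The mitochondrial ribosomal RNAs, chosen after their values were seen, were higher in isp-1: MTCE.7 went from 53.1 to 216 FPKM (log2 fold 2.02) and MTCE.33 from 34.4 to 129 (1.90) in the authors' deposited table, both at q = 0.000982.

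The called share differed from the rest in 9 of 41 lists. Of 125 cuticle collagen genes, 58 rose, 1 fell and 66 did not pass (65 and 2 adjusted over the list alone; median log2 fold 0.69; adjusted p = 2.96e-12 by Fisher's exact test). The list was led in the authors' deposited table by col-176 (2.88), col-95 (2.66) and col-121 (2.05). Of 23 insulin signalling targets, 12 rose, 3 fell and 8 did not pass (15 and 3 adjusted over the list alone; adjusted p = 8.23e-06 by Fisher's exact test). They included sod-3, cdr-2 (3.42) and dod-22 (3.03) in the authors' deposited table. Of 51 UDP-glucuronosyltransferase features, 18 rose and 6 fell (21 and 8 adjusted over the list alone; adjusted p = 1.65e-05 by Fisher's exact test), and of 48 cytochrome P450 genes 16 rose and 6 fell (17 and 9; adjusted p = 6.24e-05). Examples in the authors' deposited table were ugt-62, from 52.8 to 257 FPKM (log2 fold 2.28), ugt-61 (2.22) and cyp-33C8 (3.69). Of 35 glutathione transferase genes, 11 rose and 0 fell (16 adjusted over the list alone), a share not past the threshold in both directions together (adjusted p = 0.116 by Fisher's exact test) and past it for rises alone (0.00831). Lysosomal genes held 13 rises and 2 falls of 44 (15 and 4 adjusted over the list alone; adjusted p = 0.0451 by Fisher's exact test), with asp-8 (3.32) and asp-10 (1.97) higher in the authors' deposited table. C-type lectins rose in 20 and fell in 18 of 84 cases (22 and 18 adjusted over the list alone; adjusted p = 1.80e-07 by Fisher's exact test), and antimicrobial effectors in 11 and 9 of 57 (14 and 10; adjusted p = 0.0138).

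Of 32 proteasome genes, 19 fell, 0 rose and 13 did not pass (28 falls adjusted over the list alone; median log2 fold -0.39; adjusted p = 3.15e-06 by Fisher's exact test). Of these, rpn-9 fell by 0.59 and pas-5 fell by 0.57 at q = 0.000982 in the authors' deposited table. Of 70 cytosolic ribosome genes, 26 fell, 1 rose and 43 did not pass (57 falls and 2 rises adjusted over the list alone; median -0.35, and -0.077 with quantile normalization; adjusted p = 0.000338 by Fisher's exact test). Here rpl-25.2 fell by 0.55 and rpl-25.1 rose by 0.59 in the authors' deposited table. An excess of calls in these 2 lists did not pass with calls at 0.01 or with a log2 fold of at least 1. Of 39 oocyte and germline genes, 13 fell and 26 did not pass (19 falls adjusted over the list alone). The share was not past the threshold in both directions together (adjusted p = 0.0697 by Fisher's exact test) and was for falls alone (adjusted p = 7.53e-06). Among them were cey-2 (-0.62, q = 0.000982) and cey-3 (-0.52, q = 0.00252) in the authors' deposited table. Among the tissue lists, the median log2 fold was -0.30 for oocyte and germline genes, 0.13 for muscle, 0.16 for intestine, 0.37 for neurons and 0.45 for hypodermis and seam. With quantile normalization these medians were -0.22, 0.046, 0.11, 0.12 and 0.17. Of 6 vitellogenin genes, 3 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.158, and 0.0295 for falls alone, by Fisher's exact test): vit-3, vit-1 (-1.42) and vit-4 (-1.28), each at q = 0.000982 in the authors' deposited table. In lipid metabolism, acs-2, an acyl-CoA synthetase of fatty acid oxidation, rose 9.16-fold from 12.9 FPKM and fat-5 fell by 1.54. Also, the gluconeogenic gene pck-1 (1.82) and the glyoxylate cycle gene icl-1 (1.76) rose, all at q = 0.000982 in the authors' deposited table. The genes acs-2, fat-5, pck-1 and icl-1 were chosen here after their values were seen.

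**Figure D3:**
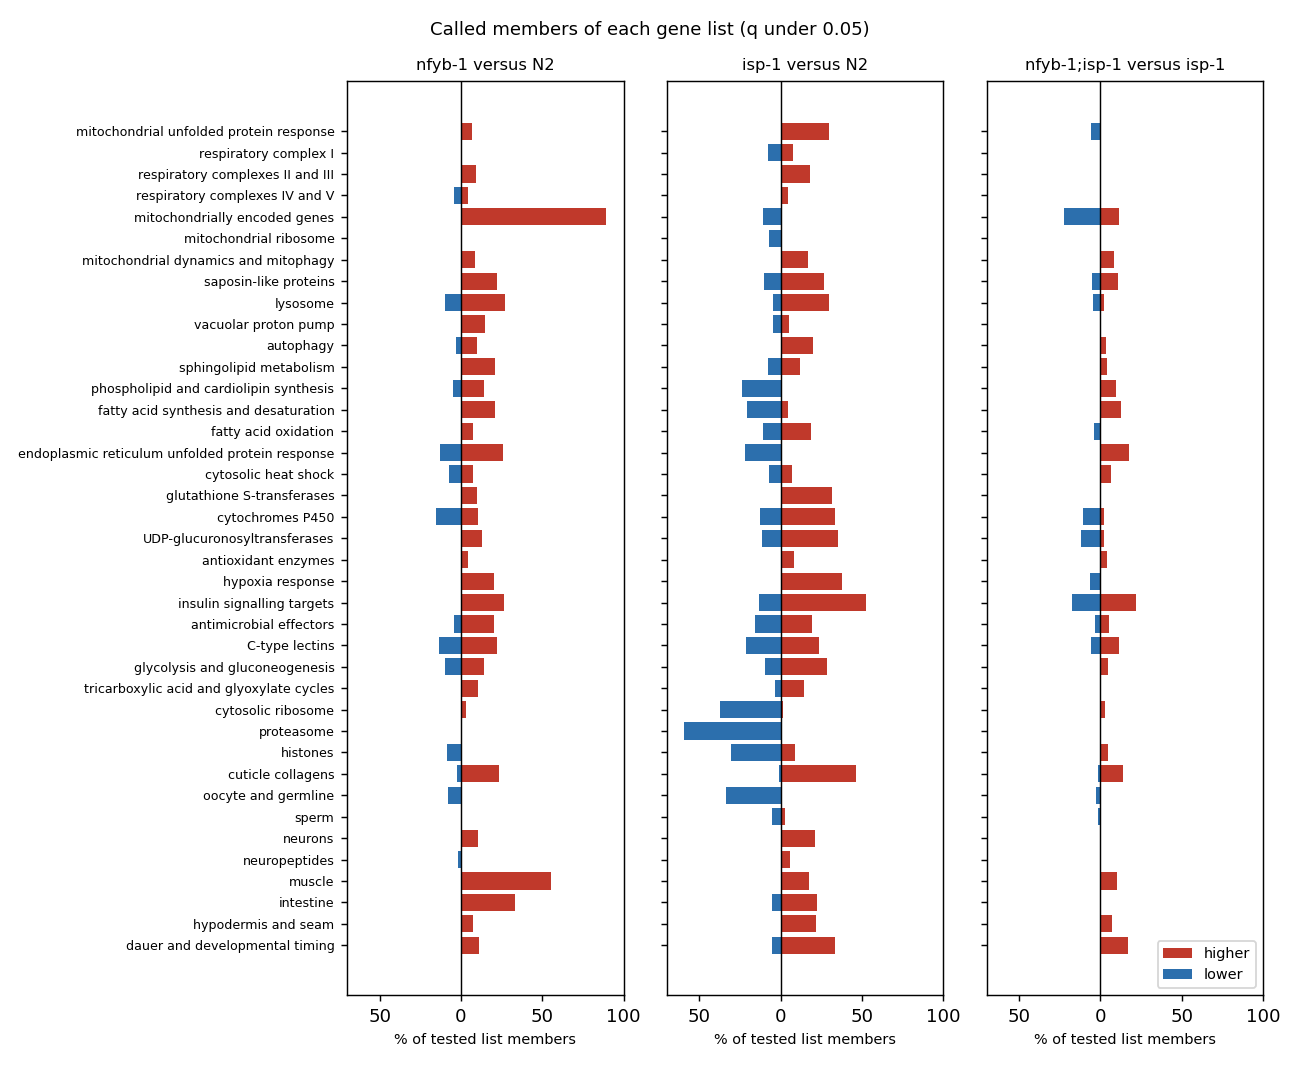
Percent of the tested members of 39 gene lists with at least 9 tested members that were higher (to the right of 0) or lower (to the left) at q under 0.05 in the authors' deposited table, for 3 comparisons. Mitochondrially encoded genes reach 8 of 9 in nfyb-1 versus N2, and the proteasome 19 falls of 32 in isp-1 versus N2.

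In nfyb-1;isp-1 animals against isp-1, which asks what nfyb-1 changes in the long-lived background, spp-8 rose from 48.7 to 295 FPKM (log2 fold 2.60, q = 0.000982) in the authors' deposited table. Of the lists, 18 of 129 cuticle collagen and 4 of 23 ER stress genes also rose, and 6 of 50 glucuronosyltransferase features and 5 of 46 cytochrome P450 genes fell. There were 263 rises and 121 falls among 12351 tested features at q under 0.05 in the authors' deposited table, and 118 and 59 with the p-values adjusted within this comparison alone, an alternative added after the data were seen. Calls at q of 0.01 or more in this comparison, such as hsp-4, col-74, cld-1 and spig-4 below, did not pass that adjustment. The largest rises there, besides spp-8, were the inositol transporter gene hmit-1.1 (2.72), col-74 (2.44, q = 0.0154), col-165 from 17.7 to 92.7 FPKM (2.39), the arginine kinase gene argk-1 (2.38) and col-43 (2.34), the others at q = 0.000982. The largest falls in the authors' deposited table, besides nfyb-1, were cld-1 (-5.28, q = 0.0372), spig-4 (-3.47, q = 0.0461), exh-1 (-3.43, q = 0.00321), clec-190 (33.1 to 3.87 FPKM, q = 0.00507) and hrg-3, from 51.3 FPKM (-2.29, q = 0.000982). Among the fixed genes, hsp-4 rose by 0.60 (q = 0.0400), and hsp-6 (0.08, q = 0.843), hsp-60 (0.11, q = 0.719), spp-10 (0.39, q = 0.145), gst-4 (-0.01, q = 0.979), sod-3 (-0.47, q = 0.152), hlh-30 (0.35, q = 0.176) and vit-2 (0.21, q = 0.828) were not called in the authors' deposited table.

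The called share differed from the rest in 7 of 41 lists. Of 129 collagen genes, 18 rose, 2 fell and 109 did not pass (18 and 3 adjusted over the list alone; adjusted p = 1.13e-07 by Fisher's exact test). Here dpy-17 rose from 128 to 363 FPKM and sqt-3 from 142 to 367 (1.37) in the authors' deposited table. Of 23 ER stress genes, 4 rose and 19 did not pass (4 rises and 2 falls adjusted over the list alone; adjusted p = 0.0299 by Fisher's exact test): dnj-7 (0.70), xbp-1 (0.63), pdi-6 (0.60) and hsp-4 in the authors' deposited table. This share did not pass with calls at 0.01 or with a log2 fold of at least 1. The Gene Ontology term for the ER unfolded protein response, tested after the data were seen, covers more features. Of these, 13 of 45 rose here and 16 of 41 in nfyb-1 versus N2 (adjusted p = 1.21e-10 and 1.20e-07 by Fisher's exact test for rises). The term did not pass for falls in either comparison. Insulin signalling targets went both ways, with 5 rises and 4 falls of 23, also adjusted over the list alone (adjusted p = 2.82e-07 by Fisher's exact test). The metallothionein gene mtl-1 (1.98), fat-5 (1.81) and the lysozyme gene lys-7 (1.46) rose and dod-24 fell from 46.0 to 14 FPKM (-1.71) in the authors' deposited table, each at q = 0.000982. Of 50 UDP-glucuronosyltransferase features, 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00859 by Fisher's exact test). Of these, ugt-12 (-1.18) and ugt-4 (-1.15) were lower in the authors' deposited table. Of 46 cytochrome P450 genes, 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0194 by Fisher's exact test). Here cyp-13A7 (-1.77) and cyp-13A5 (-1.17) were lower and cyp-14A5 (1.04) was higher in the authors' deposited table. C-type lectins held 8 rises and 4 falls of 70 (9 and 5 adjusted over the list alone; adjusted p = 1.96e-05 by Fisher's exact test).

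Of 9 mitochondrially encoded features, 2 fell and 1 rose, also adjusted over the list alone, with a median log2 fold of -0.47 (adjusted p = 0.0179 by Fisher's exact test). These were nduo-2 (-0.66, q = 0.0166), nduo-4 (-0.58, q = 0.0363) and the merged ndfl-4,nduo-6 (1.26, q = 0.0300) in the authors' deposited table. Of 44 lysosomal genes, 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.427 by Fisher's exact test): cpr-1 (0.71), asp-10 (-1.04) and asp-8 (-0.80) in the authors' deposited table. Muscle genes held 3 rises of 29, also adjusted over the list alone (adjusted p = 0.205 by Fisher's exact test), led by tnt-4 (0.88) in the authors' deposited table.

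The isp-1 mutation was also read in the nfyb-1 background, as nfyb-1;isp-1 against nfyb-1, with 1453 rises and 640 falls among 12274 tested features in the authors' deposited table. The largest rises were fmo-2 (6.77, q = 0.0112), col-74 (5.92, q = 0.00179), col-165 (5.67), the cuticlin gene cut-3 (5.34, q = 0.00321), pqn-73 (4.46) and mtre-1 (4.29, q = 0.0121), the others at q = 0.000982 in the authors' deposited table. The largest falls were fat-7 (-5.63), cyp-35A3 (-3.07), asp-12 (-3.03), vit-3 (-2.59), the lysozyme gene ilys-5 (-2.55) and ssp-11 (-2.48, q = 0.0360), the others at q = 0.000982 in the authors' deposited table. Collagens rose in 52 and fell in 3 of 129 cases (62 and 5 adjusted over the list alone; adjusted p = 2.66e-10 by Fisher's exact test). Insulin signalling targets held 11 rises and 3 falls of 22 (14 and 3 adjusted over the list alone; adjusted p = 1.87e-05 by Fisher's exact test), including sod-3 (3.26) in the authors' deposited table. Cytochrome P450 genes held 15 rises and 10 falls of 44 (19 and 11; adjusted p = 5.56e-08 by Fisher's exact test), including cyp-13B1 (4.14), in the authors' deposited table. Of 9 mitochondrially encoded features, 4 fell, among them nduo-2 (-1.38) and ctb-1 (-1.22) in the authors' deposited table. Adjusted over the list alone, 6 fell and 1 rose (median -1.04; adjusted p = 0.141, and 0.0102 for falls alone, by Fisher's exact test). Of 32 proteasome genes, 3 fell (7 adjusted over the list alone; adjusted p = 0.573 by Fisher's exact test), while all 32 were lower with a median of -0.38, beside -0.39 for isp-1 versus N2, a difference that was not tested. Of 70 cytosolic ribosome genes 1 rose and 0 fell, also adjusted over the list alone, fewer calls than elsewhere (adjusted p = 0.000371 by Fisher's exact test). Among the fixed genes, hsp-4 fell by 0.57 (q = 0.0498), spp-10 rose by 0.59 (q = 0.0196), and spp-8 (0.84), gst-4 (1.58) and hlh-30 (0.75) rose at q = 0.000982 in the authors' deposited table. Not called there were hsp-6 (0.63, q = 0.102), hsp-60 (0.12, q = 0.634) and vit-2 (0.49, q = 0.614).

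Against N2, nfyb-1;isp-1 animals had 2048 rises and 1327 falls among 12394 tested features in the authors' deposited table. The largest rises there were fmo-2 (5.24), cyp-13B1 (4.72), pals-6 (4.58, q = 0.0159), argk-1 (4.47), amt-1 (4.28) and comt-4 (4.19, q = 0.00929), the others at q = 0.000982. The largest falls in the authors' deposited table were fat-7 (-5.09), exh-1 (-3.96), asp-12 (-3.45), nfyb-1 (-3.43), cyp-35A3 (6.52 to 0.662 FPKM) and anp-1 (-3.06), all at q = 0.000982. The fixed genes spp-8 (3.60, q = 0.000982), spp-10 (0.75, q = 0.00252), hlh-30 (1.24, q = 0.000982), sod-3 (3.71, q = 0.000982), gst-4 (2.17, q = 0.000982) and hsp-6 (0.79, q = 0.0422) rose in the authors' deposited table, whereas hsp-4 (-0.06, q = 0.813), hsp-60 (-0.033, q = 0.901) and vit-2 (0.66, q = 0.491) were not called. Collagens rose in 62 and fell in 1 of 129 cases (77 and 1 adjusted over the list alone; adjusted p = 4.57e-06 by Fisher's exact test), and 16 of 32 proteasome genes fell (24 adjusted over the list alone; adjusted p = 0.0372, and 1.27e-06 for falls alone, by Fisher's exact test). The 2-sided result for the proteasome did not pass with calls at 0.01, with a log2 fold of at least 1 or with a mean of at least 5 FPKM.

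The nfyb-1 effect was then compared between backgrounds with disjoint libraries. Across 11268 features with a fold in both, Pearson's r was 0.21 and Spearman's rho 0.29; these are across features, which are not independent replicates. Of 680 rises and 270 falls against N2 among 11285 features tested in both, 83 also rose and 14 also fell against isp-1, where independent lists would share 13.3 and 2.34. Opposite calls numbered 21. Of 676 rises with a fold, 531 were also positive against isp-1, and their median log2 fold was 0.59 in the N2 and 0.24 in the isp-1 background. Since these features were picked in the N2 background, selection alone gives smaller folds in the other. Features apart in N2, described below, cannot be among the shared calls, since they have no call between mutants. The isp-1 effect compared in the same way gave r = 0.71 and rho = 0.69 across 11671 features. Of 1379 rises and 736 falls against N2 among 11725 features tested in both, 845 also rose and 289 also fell against nfyb-1, where independent lists would share 161 and 39.5, and 3 calls were opposite. Of the isp-1 rises and falls, 61.3% and 39.3% thus kept the direction and the threshold. The median log2 fold of the isp-1 rises with a fold was 1.05 in the N2 and 0.77 in the nfyb-1 background.

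The authors' deposited table holds no test of the interaction. An approximate test, added after the data were seen, took a standard error for each log2 fold from the deposited statistic and compared the nfyb-1 effect between backgrounds. The effects differed in 129 of 11268 features at an adjusted threshold of 0.05, of which 57 had the more positive effect in the isp-1 background and 72 the more negative. Among protein genes with a symbol and at least 5 FPKM in a genotype, the largest positive differences were in pud-1.2 (4.61 on the log2 scale), cut-3 (4.11), col-165 (3.92), nlp-61 (2.97), pmk-3 (2.17) and dpy-17 (2.04). The largest negative differences were in dod-24 (-3.99), hrg-3 (-2.87), hrg-2 (-2.81), fbxa-192 (-2.47), the ion channel gene acd-1 (-2.45) and tiar-2 (-2.43). For dod-24 the authors' deposited table gave 10.1 FPKM in N2, 48.9 in nfyb-1, 46.0 in isp-1 and 14 in nfyb-1;isp-1. The spp-8 effects, 2.75 and 2.60, differed by -0.15 with a standard error of 0.23. With the deposited statistic read directly as a normal deviate, the count was 9, so the number of features rests on that scale. Of the genes named here, col-165, pmk-3, dpy-17, dod-24 and tiar-2 passed on that reading and the others did not.

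**Figure D4:**
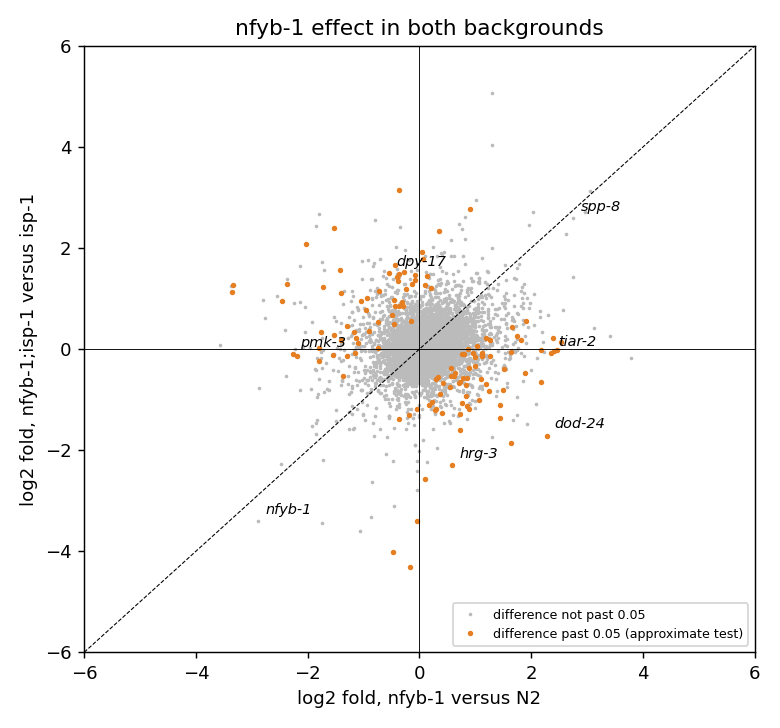
Log2 fold of nfyb-1 versus N2 (x axis) against nfyb-1;isp-1 versus isp-1 (y axis) for the features with a fold in both; points are features, orange where the approximate test of the difference passed 0.05, the dashed line marks equal effects, and 2 features lie outside the axes. spp-8 and nfyb-1 lie near the dashed line, and dod-24 and dpy-17 have opposite signs in the 2 backgrounds.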

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

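All tests in this part were chosen after the results were seen. The nfyb-1 effect differed between the N2 and the isp-1 background in 16 named genes by the approximate test of the difference, given here as the effect in isp-1 minus that in N2 on the log2 scale. With the statistic read as a normal deviate, 5 of them passed (col-165, dod-24, dpy-17, pmk-3 and tiar-2) and 11 did not. The difference was positive in pud-1.2 (4.61), cut-3 (4.11), col-165 (3.92), nlp-61 (2.97), pmk-3 (2.17), dpy-17 (2.04), col-43 (2.0), pmk-2 (1.82) and pud-3 (1.56). It was negative in dod-24 (-3.99), hrg-3 (-2.87), hrg-2 (-2.81), fbxa-192 (-2.47), acd-1 (-2.45), tiar-2 (-2.43) and haf-6 (-2.19). Except for col-43, pmk-2, pud-3 and haf-6, these genes are the largest differences listed above, which were picked by this same difference. Their passing is therefore not separate evidence, and the count of 16 does not give a rate among named genes. In pmk-3, pmk-2, pud-3, fbxa-192, tiar-2 and haf-6 the effect in the isp-1 background lay between -0.24 and 0.03, and both single mutants differed from N2.

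The first pattern is that of genes called apart between N2 and all 3 mutants, with no call between mutants. The absence of a call does not show that the mutants share 1 level. Some members stood at similar levels in the mutants, as tiar-2, and others changed in steps. T21H3.1, chosen after its values were seen, stood at 460 FPKM in N2, 748 in nfyb-1, 830 in isp-1 and 1240 in nfyb-1;isp-1 in the authors' deposited table. Of 11071 features tested in every comparison, 196 differed between N2 and each mutant in the same direction with no call between mutants, against 45, 26 and 45 that set apart nfyb-1, isp-1 and nfyb-1;isp-1. Chance values of the N2 libraries, which these comparisons share, are argued against as the whole cause, since chance alone allows 79.2 features past the threshold in a comparison with N2. Effects of both mutations that add up stay open: the approximate test of the difference passed for 27 of 195 members, with 6.45 false calls expected over all features, but for 2 with the statistic read as a normal deviate, and the members were chosen partly by the contrast it tests. A stretch of the genome that differs between the N2 stock and the mutants remains a candidate explanation for a part. Of the features, 14.8% had another within 20 kb. Draws from all features called in a single mutant had a median of 8.67% and an upper limit of 14.3%. Of 18 features tested within 50 kb of isp-1, 4 (islo-1, pmk-1, pmk-2 and pmk-3) were in the set, against 0 of 9 within 50 kb of nfyb-1. These 4 genes lie side by side, and neighbours were counted singly. Both measures therefore cannot tell a differing stretch from neighbours regulated together. In nfyb-1, which lacks the isp-1 mutation, pmk-3 also fell, from 40.7 to 8.47 FPKM, so nearness to that mutation does not account for it. A response shared by both mutations and a difference in the handling of the N2 animals also stay open.

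The second pattern is the rise of mitochondrially encoded mRNAs in nfyb-1 and their lower median level in nfyb-1;isp-1 than in nfyb-1. In the latter comparison not all were called lower, as ctc-1 (log2 fold -0.63, q = 0.329). The merged ndfl-4,nduo-6 was higher there (1.08, q = 0.0656, not called), in the authors' deposited table. A common factor on the poly(A)-selected signal of all RNA of that genome is argued against in nfyb-1;isp-1 versus nfyb-1. There both ribosomal RNAs rose by 1.38 on the log2 scale in the authors' deposited table and the mRNAs had a median of -1.04. In nfyb-1 versus N2, where the mRNAs had a median of 0.56, such a factor stays open because the ribosomal RNAs went apart. In the authors' deposited table MTCE.33 fell by 0.54 (q = 0.00831) and MTCE.7 went from 53.1 to 67.9 FPKM (log2 fold 0.35, q = 0.0860, not called). A change in the number of mitochondria together with their nuclear-encoded respiratory subunits is argued against by medians of 0.069 (0.033 to 0.11) and 0.16 (0.087 to 0.26) over 46 such subunits in the same 2 comparisons. An effect of nfyb-1 that depends on isp-1 stays open as a biological explanation, and so does a change in polyadenylation, on which poly(A) selection depends and which was not tested.

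The third pattern is the rise of cuticle collagens. The oocyte and germline genes had medians of -0.17 in nfyb-1 versus N2 (34 of 39 lower, 3 called) and -0.30 in isp-1 versus N2, so a smaller share of germline RNA may contribute. Sperm genes had medians of 0.064 and -0.15 in these comparisons. As the whole cause, a smaller germline share would raise every somatic tissue alike if the listed genes had no germline RNA, which was not tested. Under that condition it is argued against in nfyb-1 versus N2. There the medians of collagens (0.34), muscle (0.41), intestine (0.30), hypodermis and seam (0.20) and neurons (0.077) had a range of 0.33. Permutation of list membership, which takes genes as independent, gave p = 0.0052. With quantile normalization these medians were 0.26, 0.33, 0.25, 0.090 and 0.036. The same cause is left open in isp-1 versus N2, where the medians, 0.69, 0.13, 0.16, 0.45 and 0.37, had a range of 0.56 (permutation p = 0.103). Collection at a younger stage would lower the vitellogenins: in nfyb-1 versus N2 0 of 6 were called lower and the median was 0.046, which argues against it there. In isp-1 versus N2, 3 of 6 were called lower with a median of -0.93 (-2.05 to 0.40), as a younger stage would give. However, 2 of the 6 were higher, without a call, and the interval holds 0. Staging may thus contribute to that comparison but is not settled by these genes, and the genotype itself stays open in both. Staging of nfyb-1;isp-1 was not tested and stays open for the cuticle genes that rose in it.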

How the results depend on the processing

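No paired analysis was possible because the deposited values merge the 3 libraries of a genotype. For the same reason the other count tool, other count normalization, limma on FPKM, no low filter, a fit of 2 groups and leaving out a library were not run. In the order nfyb-1 versus N2, isp-1 versus N2, nfyb-1;isp-1 versus isp-1, nfyb-1;isp-1 versus nfyb-1 and nfyb-1;isp-1 versus N2, a threshold of 0.01 left 551, 1289, 177, 1160 and 1970 called features, and an absolute log2 fold of at least 1 left 220, 962, 194, 998 and 1461. The stricter rule itself sets these counts. Alternatives added after seeing the data kept the counts within 1.5 times, except adjustment within nfyb-1;isp-1 versus isp-1 alone, which left 177 of 384. The number of lists past the threshold went from 11 to 2 in nfyb-1 versus N2 and from 7 to 11 in nfyb-1;isp-1 versus nfyb-1 with a log2 fold of at least 1, and from 10 to 6 in nfyb-1;isp-1 versus N2 with a mean of at least 5 FPKM; the cause was not tested. Of 44 list results past the threshold, 10 did not pass with calls at 0.01, 7 with a mean of at least 5 FPKM and 15 with a log2 fold of at least 1. Those lost at 0.01 were the mitochondrial ribosome, cytochromes P450 and sperm in nfyb-1 versus N2, the cytosolic ribosome and the proteasome in isp-1 versus N2, mitochondrially encoded and ER stress genes in nfyb-1;isp-1 versus isp-1, the cytosolic ribosome in nfyb-1;isp-1 versus nfyb-1, and the proteasome and sperm in nfyb-1;isp-1 versus N2. The filter on the mean removed cytochromes P450 in nfyb-1 versus N2 and in nfyb-1;isp-1 versus isp-1, the lysosome in isp-1 versus N2, and glucuronosyltransferases, insulin signalling targets, the proteasome and neuropeptides in nfyb-1;isp-1 versus N2. In nfyb-1 versus N2, C-type lectins and antimicrobial effectors alone passed with a log2 fold of at least 1. That rule also removed the proteasome in isp-1 versus N2, mitochondrially encoded and ER stress genes in nfyb-1;isp-1 versus isp-1, and the proteasome, sperm and neuropeptides in nfyb-1;isp-1 versus N2. With a log2 fold of at least 1, the cytosolic ribosome in isp-1 versus N2 was called less often than other features (adjusted p = 0.0244 by Fisher's exact test), since its falls were small.

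The correlation of the nfyb-1 effects was 0.19 with quantile normalization, 0.24 with a pseudocount of 1 and 0.33 over features with a mean of at least 5 FPKM, and that of the isp-1 effects 0.68, 0.72 and 0.78; the cause was not tested. The approximate interaction count was 9 with the statistic read as a normal deviate, 101 at a threshold of 0.01 and 112 over features with a mean of at least 5 FPKM. Quantile normalization shifted the median of all features by -0.12 in nfyb-1;isp-1 versus N2 and by less than 0.1 elsewhere, but moved the medians of single lists more, as for the cytosolic ribosome in isp-1 versus N2, from -0.35 to -0.077. Of 124 folds of named genes, 38 moved by more than their standard error with a pseudocount of 1 and 25 with quantile normalization, and no called fold reversed; of 81 named calls, 14 did not pass 0.01. Of the 30 largest rises and 30 largest falls, 23 and 25 stayed among the largest with a pseudocount of 1, and 28 and 25 with quantile normalization. With a pseudocount of 1, fmo-2 in nfyb-1;isp-1 versus nfyb-1 went from 6.77 to 4.61 and cld-1 in nfyb-1;isp-1 versus isp-1 from -5.28 to -2.97. Unknown depth limits what can be said of low values and of the 92 of 9751 protein features with at least 5 FPKM in a genotype that were listed at 0 in another.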

Other observations

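The tests of terms below were chosen after the data were seen. Gene Ontology terms in the authors' table described groups outside the fixed lists (Fisher's exact test, adjusted over 718 to 740 terms). In nfyb-1 versus N2, 29 of 52 features annotated to membrane rafts rose (adjusted p = 3.54e-19 by Fisher's exact test), 54 of 204 of the innate immune response (4.09e-18), 13 of 20 serine carboxypeptidases (2.31e-09) and 8 of 19 of the basement membrane (0.000530). Rafts, innate immunity and carboxypeptidases were not particular to nfyb-1. In isp-1 versus N2, 24 of 53, 66 of 213 and 11 of 20 such features rose (adjusted p = 1.89e-07, 7.03e-12 and 0.000197 by Fisher's exact test). None of these terms passed for rises in nfyb-1;isp-1 versus isp-1. In isp-1 versus N2, 69 of 315 sequence-specific transcription factors rose (adjusted p = 3.74e-05 by Fisher's exact test), whereas 19 of 40 translation initiation factors (2.44e-09), 15 of 30 genes of unfolded protein binding (3.87e-08) and 20 of 60 P granule genes (2.12e-07) fell. In nfyb-1;isp-1 versus N2, 15 of 38 genes of the meiotic cell cycle and 16 of 45 of DNA replication fell (adjusted p = 0.000724 and 0.00134 by Fisher's exact test), and 14 of 28 genes of the muscle M band rose (0.00144). There, 19 of 42 features of the molting cycle of the cuticle also rose (adjusted p = 0.000514 by Fisher's exact test). In nfyb-1;isp-1 versus nfyb-1, 7 of 11 features of the molting cycle process rose (adjusted p = 0.00279 by Fisher's exact test).

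In autophagy and lipid handling, the genes sqst-1 and asah-1 were chosen after their values were seen. The receptor gene sqst-1 stood at 16.7 FPKM in N2, 23.9 in nfyb-1, 55.5 in isp-1 and 83.1 in nfyb-1;isp-1 in the authors' deposited table. It was called in every planned comparison. The acid ceramidase gene asah-1 followed the same order, at 18.4, 28.3, 39.6 and 59.0 FPKM in the authors' deposited table. Among the neuronal list, 8 of 20 genes rose in nfyb-1;isp-1 versus N2 and 0 fell (11 rises adjusted over the list alone), and 7 of 14 hypodermis and seam genes rose and 1 fell (11 and 1), with adjusted p = 0.482 and 0.0996 by Fisher's exact test, and 0.0363 and 0.0177 for rises alone. The filamin gene fln-2, chosen after its values were seen, stood at 8.86 FPKM in N2, 20.3 in nfyb-1, 20.7 in isp-1 and 24.2 in nfyb-1;isp-1 in the authors' deposited table.

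Lists not given above or in the report for this also passed in 1 direction alone, by Fisher's exact test with the adjusted p in parentheses. In nfyb-1 versus N2, 5 of 19 insulin signalling targets (0.0187) and 5 of 24 sphingolipid genes (0.0439) rose. In isp-1 versus N2, 6 of 16 hypoxia genes (0.0286) and 6 of 18 genes of dauer and developmental timing (0.0492) rose, and 7 of 23 histone genes (0.00379) and 5 of 21 of phospholipid synthesis (0.0482) fell. In nfyb-1;isp-1 versus nfyb-1, 6 of 16 hypoxia genes (0.0390) and 10 of 37 glutathione transferase genes (0.0412) rose, and 3 of 6 vitellogenins (0.0257), 5 of 21 genes of phospholipid synthesis (0.0315) and 5 of 24 of fatty acid synthesis (0.0482) fell. In nfyb-1;isp-1 versus N2, 8 of 18 genes of dauer and developmental timing rose (0.0206). Rises were rarer than elsewhere among 68 mitochondrial ribosome genes, with 0 in isp-1 versus N2 (0.00336), nfyb-1;isp-1 versus nfyb-1 (0.00438) and nfyb-1;isp-1 versus N2 (0.000177), among sperm genes in nfyb-1;isp-1 versus nfyb-1 (2 of 74, 0.0422) and among oocyte and germline genes in nfyb-1;isp-1 versus N2 (1 of 39, 0.0447).

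Features listed at 0 were short: of 9751 protein features with at least 5 FPKM in a genotype, the longest annotated transcript had a median of 1382 nucleotides, against 422.5 nucleotides for the 92 of them listed at 0 in another genotype. Of these, 44 were at 0 in N2, 58 in nfyb-1, 32 in isp-1 and 18 in nfyb-1;isp-1. The antimicrobial peptide gene fipr-18, chosen after its values were seen, stood at 18.3 FPKM in N2 and was listed at 0 in the 3 mutants in the authors' deposited table, and T24A6.1, chosen likewise, was listed at 0 in N2 and stood at 22.3, 26.2 and 22.7 FPKM in nfyb-1, isp-1 and nfyb-1;isp-1.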
